A study of Mus musculus with 54 samples.

How the data were processed

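Gene expression was measured on Affymetrix Mouse Gene 1.1 ST arrays in total RNA from 7 tissues of C57BL/6 mice that swam or did not. Per the labels, swimming lasted 3 weeks with 2 sessions per day of 90 minutes and 4 hours of rest between them, after 9 days of acclimation in which sessions grew by 10 minutes per day, and the mice were 14 weeks old. RNA was extracted with Trizol and labelled with biotin. The labels give no batch, no date, no time of day of tissue collection and no statement whether tissues came from the same mice, so the 54 arrays were treated as independent.

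The deposited values were intensity values of 25917 probe sets on a linear scale. Per the submitters' processing notes, PLIER and limma were used, and their versions, settings and the genome build were not given in the sources used here. The design fixed before the data were examined assumed values already normalized between arrays. The values showed otherwise, since 75th percentiles of arrays of the same group differed by up to 1.89-fold. Quantile normalization within each tissue of log2(signal + 16) was therefore used throughout, with the values as deposited and arrays centred on their medians as alternatives. The tests, the gene lists, the rule for named genes and most alternatives were also fixed before the data were examined, and alternatives added later are named as such.

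Of the probe sets, 21086 carried 1 gene symbol, 1867 carried several and 2964 carried none, and the last 2 kinds were left out of the gene tests. Symbols numbered 18759. Within each tissue the lowest 40% of probe sets by mean signal were left out, and the probe set of highest mean stood for its gene. Genome positions are not given, because the annotation at hand could not be tied to the build behind the probe sets. Members of families with near-identical sequences (such as Cyp4a, Saa, Ces, Ugt2b, Sly) may share probes, so their values are uncertain as to the member. Sharing of probes between related genes was not tested for any gene, Hamp2 included. The words "not annotated as protein-coding" rest on the annotated gene type.

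Each tissue was fitted apart in R 4.3.3 with limma 3.58.1 (lmFit and eBayes, default settings), as swim minus control, two-sided, with Benjamini-Hochberg adjustment over genes and a threshold of 0.05. Statmod 1.5.0 served the robust fits and matplotlib 3.10.9 the plots. Across all 54 arrays and 14 group means, limma tested whether the swimming effect differed between the 7 tissues (an F test over 6 contrasts), the average effect over the 6 organs outside muscle, and the difference between the visceral and subcutaneous fat effects. Similarity between the 21 pairs of tissues was the correlation of log2 fold changes across genes, with a permutation test of 100 draws of the swim and control labels within tissues. Genes are not independent replicates in such a correlation.

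The 65 gene lists, 33 of function and 32 of cell composition, held 1389 names, of which 1242 were matched on the array. Lists with at least 5 measured genes were tested per tissue with limma's camera at a preset correlation of 0.01, with an estimated correlation and with fry as alternatives. Of the 93 list shifts called with the preset correlation, 0 held with an estimated correlation and 36 held with fry, which called 41 lists in all. Each list's adjusted p with an estimated correlation is therefore given in the text.

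Named genes were chosen by rule. For each tissue these were the 10 largest rises and the 10 largest falls among genes that passed and whose swim and control arrays did not overlap, and where fewer than 5 passed in a direction, those of smallest p up to 5. They also included up to 4 members of smallest p from each list that passed or that held 3 or more called genes, the 10 genes of smallest p in each test across tissues, the organ and sex markers, and members of the clock and glucocorticoid lists called in 3 or more tissues. The text names a part of them. Genes outside this rule are said to be chosen after their values were seen.

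The tests were checked on simulated data with the same group sizes and 200 changed genes in each tissue. Noise was drawn independently for each probe set, so differences shared by many genes of an array were not simulated. False calls may therefore be more frequent in real arrays than in these simulations. Of genes changed by 1 log2 unit the test found 29.9% in subcutaneous fat and between 80.6% and 89.6% in the other 6 tissues, and with no change simulated it called 0 genes, with the same limma test, in each tissue. A separate simulation changed 200 genes by 1 log2 unit in the 6 organs outside muscle and 200 others in kidney alone, among 14873 genes. In it the F test across tissues, which pools the spread of all tissues, found 359 of these 400 and called 410 unchanged genes, 53.3% of its calls, and a version with each tissue's own spread found 387 and called 63 unchanged genes, or 14.0%. Alternatives tried were other scalings, a pseudocount of 1, no filter and a 60% filter, other ways to combine probe sets, limma's trend and robust options, array weights, 1 fit of all arrays, and each array left out in turn. Those added after the data were seen were protein-coding genes alone, the array's signal range or the B cell list mean as a covariate, genes brighter in another tissue left out, and 3 other treatments of spread across tissues. The number of arrays limits the precision.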

Results

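The 54 arrays covered visceral fat, subcutaneous fat, kidney, spleen and brain with 4 control and 4 swim arrays each, liver with 3 control and 4 swim arrays, and muscle with 4 control and 3 swim arrays. The median probe set signal per array lay between 45.92 and 118.65 intensity units. Organ markers stood highest in their own tissue. On the log2 scale Alb averaged 13.40 in liver, Umod 15.31 in kidney, Snap25 14.00 in brain, Ckm 14.03 in muscle and Adipoq 12.88 in visceral fat. The series title asks about responses to exercise in organs other than muscle, and each tissue comparison asks which genes differed between swim and control mice. Values after gene symbols are log2 fold changes of swim over control with the SE of the limma fit. For each named gene that passed the adjusted threshold within a tissue, all swim arrays lay on one side of all control arrays.

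In visceral fat, circadian clock genes showed the largest changes. Ciart (probe set 10373452), a repressor within the clock, rose by 2.95 ± 0.12 (n = 4 control and 4 swim, limma adjusted p = 1.55e-06) and Per3 rose by 2.09. Arntl (probe set 10556463), which encodes the clock activator BMAL1, fell by 2.28 ± 0.10, and its relative Npas2 fell by 2.06 ± 0.14. Of 17 measured genes of the core clock and clock output list, 11 rose, 4 fell and 2 did not pass, against 12 and 4 adjusted over the list alone. The list rose by camera (adjusted p = 8.00e-05; adjusted p = 0.132 with an estimated correlation).

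Genes of fatty acid and triglyceride synthesis rose in visceral fat for 11 of 23 members, with 0 falls in limma and 12 that did not pass, and likewise 11 rises adjusted over the list alone. Mlxipl, a carbohydrate-responsive transcription factor, rose by 1.08 ± 0.13, Acaca by 0.72 ± 0.13, Me1 by 0.68 ± 0.16 and Dgat1 by 0.54 ± 0.09. The list median of 0.35 became -0.08 with arrays centred on their medians, where the median of all genes was -0.22, and Acaca, Me1 and Dgat1 did not pass there or with values as deposited. Of 21 angiogenesis genes, 10 rose and 2 fell (12 and 2 adjusted over the list alone), among them the Notch ligand Dll4 at 0.94 ± 0.12 and the VEGF receptor Kdr at 0.68 ± 0.07, while Angpt1 fell by 0.97 ± 0.09. Of 16 endothelial genes 8 rose and 1 fell, with the same counts adjusted over the list alone, including Egfl7 at 0.64 ± 0.08 and Cdh5 at 0.49 ± 0.08, though the list median of 0.26 became -0.06 with arrays centred on their medians. With values as deposited Kdr, Egfl7 and Cdh5 did not pass, with Cdh5 at 0.21, and with arrays centred on their medians Cdh5 did not pass, at 0.091. Camera gave adjusted p = 8.00e-05, 0.00397 and 0.0443 for these 3 lists, and adjusted p = 0.867 for each with an estimated correlation.

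Macrophage genes rose in visceral fat for 7 of 22 members and fell for 1, against 9 and 1 adjusted over the list alone. Gpnmb, a gene of lipid-laden macrophages, rose by 2.04 ± 0.35, Mpeg1 by 1.22 ± 0.20 and the lysosomal protease Ctss by 1.21 ± 0.23, while the lipopolysaccharide co-receptor Cd14 fell. Outside the list, Mmp12 rose by 1.95 ± 0.35 and Atp6v0d2 by 1.94 ± 0.29. Swim replicate 5 stood above the other 3 swim arrays for Mpeg1, at 9.17 against 8.28 to 8.35, and for Atp6v0d2, at 8.86 against 7.42 to 7.66. Of 26 immediate early genes 8 fell and 18 did not pass (8 falls and 1 rise adjusted over the list alone), with Nr4a1 down by 1.64, Egr1 by 1.41 and Fosl2 by 0.85. By camera both lists had adjusted p = 0.00290, and adjusted p = 0.867 for both with an estimated correlation. Other falls were the cell cycle inhibitor Cdkn1a at -1.82 ± 0.20, Anxa8 at -1.85, Vnn1 at -1.79 ± 0.19 and Mmp9 at -1.76 ± 0.25.

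In visceral fat 2677 of 11463 genes passed, 1295 higher and 1382 lower, and 122 of them changed at least 2-fold. Genes not annotated as protein-coding made up 100 of the rises and 11 of the falls, among them 9530091C08Rik at 1.85 ± 0.15. Swim and control arrays did not overlap for 27.2% of genes, against 2.86% by chance. The count was 601 (273 higher, 328 lower) with values as deposited, 5209 (697 higher, 4512 lower) with arrays centred on their medians, and 1695 without swim replicate 7.

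In subcutaneous fat 0 of 11548 genes passed in limma, with 2489 at an unadjusted p under 0.05. The genes of smallest p were clock and interferon genes, with Per2 (probe set 10356601) at 1.78 ± 0.22 (n = 4 and 4, limma adjusted p = 0.166), Hlf at 2.18 ± 0.32, Per3 at 2.35 ± 0.35, Oas1a at -1.24 and Irf7 at -1.47 ± 0.22. Each of these had adjusted p = 0.166. Of 17 clock genes 0 passed over all genes in limma, and 9 rose and 2 fell adjusted over the list alone. Of 23 interferon-stimulated genes 0 passed in limma, and 18 fell adjusted over the list alone, with a median of -0.97. Of 24 macrophage genes 0 passed in limma, and 16 fell adjusted over the list alone, with Itgax at -1.36 ± 0.26. For these lists camera gave adjusted p = 9.61e-05, 7.26e-14 and 9.66e-09, and adjusted p = 0.424 for each with an estimated correlation.

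Lymphocyte genes varied between arrays of the same group in subcutaneous fat. Cd79a, a subunit of the B cell receptor, stood between 11.13 and 11.26 in control replicates 18, 19 and 20, at 9.87 in swim replicate 23, at 8.60 in swim replicate 22 and between 4.43 and 5.19 in the other 3 arrays. Glycam1, a gene of lymph node venules, stood at 11.78 or above in those 5 arrays and at 6.03 or below in the other 3. The B cell list had a median of -2.28 over 14 genes and the T and NK cell list -1.86 over 18, with 0 members past the limma threshold over all genes or adjusted over the list alone. These 2 lists had adjusted p = 0.000710 and 6.78e-05 by camera, and adjusted p = 0.480 and 0.444 with an estimated correlation. Umod, a kidney gene, stood at 15.24 in swim replicate 22 and at 5.54 or below in the other 7 arrays. The muscle gene Ckm stood at 11.52 in swim replicate 23 and between 5.53 and 7.55 in the other 7. Genes of fatty acid and triglyceride synthesis had a median of 0.88 over 23 members, 2 of which rose adjusted over the list alone (camera adjusted p = 9.41e-07; adjusted p = 0.424 with an estimated correlation). The adipocyte list mean itself ranged from 9.97 in control replicate 19 to 11.96 in swim replicate 21.

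Without control replicate 17, a control array low in these lymphocyte genes, 3976 genes passed in subcutaneous fat, with 11 of 14 B cell genes and 17 of 18 T and NK cell genes lower and 10 of 16 clock genes higher. With array weights 5715 genes passed, with 1 fit of all 54 arrays 6626 and with values as deposited 4 (Hlf, Per3, 9530091C08Rik and 2310067E19Rik, the last 2 named after their values were seen). With the B cell list mean as a covariate 0 passed in limma, against 1520 at an unadjusted p under 0.05. With swim replicate 22 left out as well, 1 gene passed, Per3 at 2.02.

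**Figure D1:**
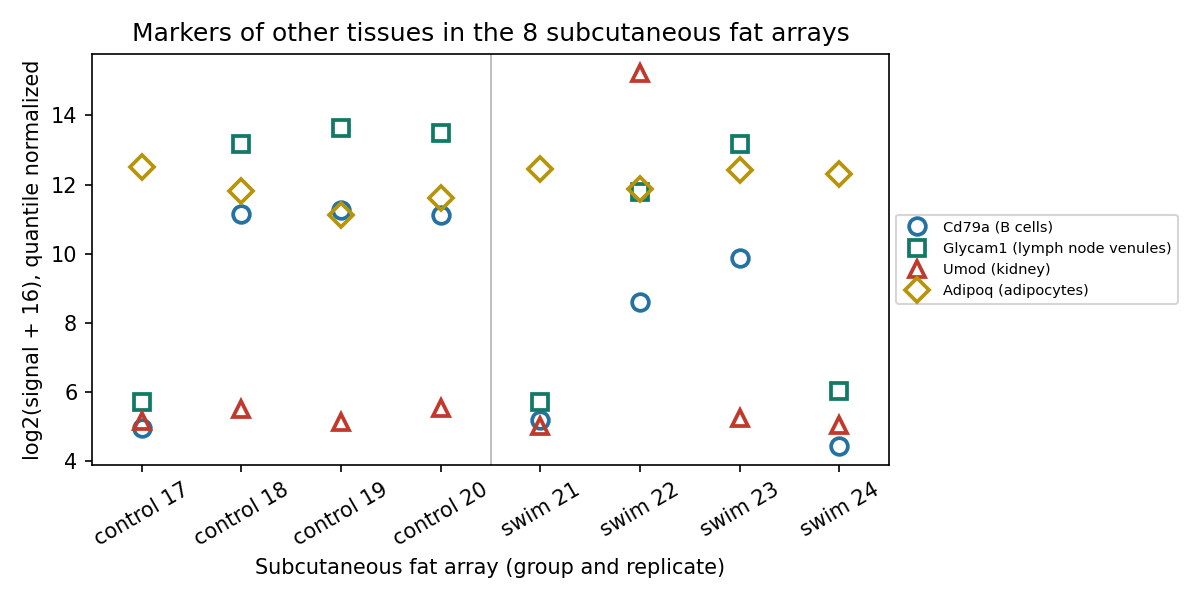
Log2 signal after quantile normalization of 4 genes (vertical axis) in each of the 8 subcutaneous fat arrays (horizontal axis, group and replicate), 1 point per array and gene. Cd79a and Glycam1 stood high in control replicates 18, 19 and 20 and swim replicates 22 and 23, and Umod reached 15.24 in swim replicate 22.

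In liver, Hamp2 (probe set 10562166), a hepcidin gene, rose by 4.37 ± 0.10 (n = 3 control and 4 swim, limma adjusted p = 4.34e-07), and Cyp4a14, a target of the fatty acid receptor PPAR-alpha, rose by 3.83 ± 0.21. The lipid transporter Mfsd2a rose by 3.02 ± 0.28 and Rgs16 by 3.15 ± 0.38. The acute phase gene Saa2 (probe set 10553274) fell by 4.46 ± 0.39, Lcn2 fell by 2.20 ± 0.24 and Saa3 fell by 1.86 ± 0.20. Of 25 acute phase and inflammatory genes 7 fell, 0 rose in limma and 18 did not pass, and 14 fell adjusted over the list alone. Of 23 interferon-stimulated genes 7 fell, with 21 adjusted over the list alone, including Rsad2 at -1.07 ± 0.19 and Dhx58 at -0.85 ± 0.12. Of 17 macrophage genes 7 fell, with 13 adjusted over the list alone, including the complement gene C1qb at -0.90 ± 0.16, Mpeg1 at -0.76 ± 0.12 and Csf1r at -0.69 ± 0.11. Camera gave adjusted p = 3.88e-10, 2.82e-13 and 4.42e-08 for these 3 lists, and adjusted p = 0.249, 0.249 and 0.260 with an estimated correlation.

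Clock genes in liver rose for 9 and fell for 4 of 17 members (12 and 4 adjusted over the list alone), with Ciart at 3.29 ± 0.18, Usp2 at 2.71 ± 0.32, Per3 at 2.03 ± 0.24 and Arntl at -2.37 ± 0.15. Of 28 genes of fatty acid oxidation and PPAR-alpha targets 4 rose, and 12 rose and 2 fell adjusted over the list alone, including the dehydrogenase Acadl at 0.57 ± 0.06. Of 23 genes of fatty acid and triglyceride synthesis 6 rose and 1 fell (12 and 1 adjusted over the list alone), including the elongase Elovl5 at 0.76 ± 0.10. Of 20 cell cycle genes 4 fell and 1 rose (13 and 2 adjusted over the list alone), with the replication helicase subunits Mcm6 at -0.57 and Mcm4 at -0.55 and with Tk1 at 0.82 ± 0.13. For these 4 lists camera gave adjusted p = 6.63e-05, 4.16e-07, 1.64e-06 and 2.13e-05, and adjusted p = 0.263, 0.249, 0.260 and 0.316 with an estimated correlation. The glucocorticoid-responsive chaperone gene Fkbp5 rose by 1.41 ± 0.17 and Cdkn1a fell by 1.73 ± 0.35. The xenobiotic-metabolising list rose for 5 of 20 members (6 adjusted over the list alone), among them Cyp2a5 at 0.60 ± 0.11 and Cyp2c29 at 0.58 ± 0.09, with adjusted p = 0.000276 by camera and adjusted p = 0.249 with an estimated correlation. Cyp2c29 did not pass with values as deposited, at 0.20, or with arrays centred on their medians, at 0.22. Skeletal muscle genes had a median of -1.27 in liver with 0 of 14 members past the limma threshold (camera adjusted p = 0.0313; adjusted p = 0.639 with an estimated correlation). The muscle gene Ckm stood at 8.32 in control replicate 52 and between 5.66 and 6.01 in the other 6 liver arrays, and without control replicate 52 that list turned direction with adjusted p = 0.0567.

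In liver 448 of 11203 genes passed, 206 higher and 242 lower, and 64 changed at least 2-fold. Swim and control arrays did not overlap for 20.6% of genes, against 5.71% by chance. The count was 135 without control replicate 49, 171 without control replicate 50, 163, 127, 237 and 250 without swim replicates 53, 54, 55 and 56, 294 with no filter, 707 with the trend and robust options and 181 (94 higher, 87 lower) with the signal range as a covariate. Of the 43 genes of the rule followed through all alternatives in liver, 22 passed without any 1 array, and Mcm6, Mcm4, Csf1r, C1qb, Mpeg1, Rsad2, Cyp2a5, Cyp2c29, Tk1 and Cdkn1a were among the 21 that did not.

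In kidney, clock genes again showed the largest changes. Npas2 (probe set 10345675) fell by 1.95 ± 0.10 (n = 4 and 4, limma adjusted p = 1.92e-05), Arntl fell by 1.37 ± 0.09, Ciart rose by 1.67 ± 0.21 and Per2 rose by 1.63 ± 0.15. Macrophage genes fell for 13 of 14 members (14 adjusted over the list alone), with Cx3cr1 at -0.84 ± 0.10, Cd68 at -0.75 ± 0.06 and Mpeg1 at -0.66 ± 0.07. Genes of MHC class II antigen presentation fell for 8 of 8 members, with the same count adjusted over the list alone, including the invariant chain Cd74 at -0.78 and H2-Aa at -0.54 ± 0.06. Interferon-stimulated genes fell for 8 of 19 members (11 adjusted over the list alone), with the interferon regulator Irf7 at -0.66 ± 0.07 and Rtp4 at -0.49 ± 0.05. Camera gave adjusted p = 5.60e-09, 7.57e-07 and 5.18e-05 for these 3 lists, and adjusted p = 0.146, 0.146 and 0.632 with an estimated correlation.

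The clock list in kidney rose for 11 and fell for 3 of 16 members, with the same counts adjusted over the list alone (camera adjusted p = 0.00113; adjusted p = 0.632 with an estimated correlation). Proteasome genes fell for 10 of 30 members (12 adjusted over the list alone), with Psmb2 at -0.39 and Psmb3 at -0.30. Heat shock genes rose for 6 of 18 members (7 adjusted over the list alone), with Dnajb1 at 0.79 ± 0.10. Cholesterol synthesis genes fell for 5 of 20 members, also 5 adjusted over the list alone, with Mvd at -0.62 ± 0.08. By camera these 3 lists had adjusted p = 0.000412, 0.0213 and 0.00358, and adjusted p = 0.638, 0.794 and 0.638 with an estimated correlation. Lcn2 fell by 1.22 ± 0.17, the chemokine Cxcl10 by 1.12 ± 0.11, Cdkn1a by 1.25 ± 0.15 and the lactate transporter Slc16a1 by 1.04 ± 0.11. The amino acid transporter Slc7a12 rose by 1.63 ± 0.25 and Cyp4a14 by 1.45 ± 0.22. Ucp1, a brown fat gene singled out after its values were seen, varied between 6.54 and 10.55 across the 8 kidney arrays and was lower in the swim arrays by a log2 change of -1.31 ± 0.52 that did not pass (limma adjusted p = 0.0959).

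In kidney 2836 of 11610 genes passed, 1258 higher and 1578 lower, and 26 changed at least 2-fold. Swim and control arrays did not overlap for 27.7% of genes, against 2.86% by chance. The count was 42 (28 higher, 14 lower) with values as deposited, 382 with 1 fit of all 54 arrays and 2791 (735 higher, 2056 lower) with arrays centred on their medians. With values as deposited Cd68, Cx3cr1, Mpeg1, Cd74, H2-Aa, Irf7, Rtp4, Psmb2, Psmb3 and Mvd did not pass, though their direction held.

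In spleen, neutrophil genes fell most. Lcn2 (probe set 10481627), which encodes lipocalin-2 of neutrophil granules, fell by 3.23 ± 0.40 (n = 4 and 4, limma adjusted p = 0.00620), the granule gene Ngp by 3.05 ± 0.44, S100a9 by 2.85 and Ltf, which encodes lactoferrin, by 2.53 ± 0.24. Of 14 genes of neutrophils and their precursors 13 fell and 1 did not pass (14 adjusted over the list alone). Of 12 genes of megakaryocytes and platelets 10 fell (11 adjusted over the list alone), with Pf4 at -1.11 and Gp9 at -1.23 ± 0.15. Of 21 macrophage genes 13 fell (15 adjusted over the list alone), with C1qa at -0.74 ± 0.15 and Adgre1 at -0.61 ± 0.12, and of 14 genes of red pulp macrophages and the marginal zone 8 fell (11 adjusted over the list alone), with Marco at -0.73 ± 0.14. Of 25 interferon-stimulated genes 14 fell (17 adjusted over the list alone), with Ifi27l2a at -0.82 ± 0.05 and Irf7 at -0.78 ± 0.07. The adjusted p by camera was 7.19e-12, 1.07e-07, 5.48e-07, 2.10e-06 and 8.48e-09 for these 5 lists, and adjusted p = 0.470 for each with an estimated correlation.

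Heat shock genes in spleen rose for 10 of 17 members (13 adjusted over the list alone), with the chaperone genes Hsph1 at 1.64 ± 0.29, Stip1 at 0.96 ± 0.13 and Dnaja1 at 0.92 ± 0.14. Of 12 clock genes 4 rose and 8 did not pass (5 rose adjusted over the list alone), with Per3 at 0.69 ± 0.09, Tef at 0.67 ± 0.12, Per2 at 0.56 ± 0.07 and Nr1d2 at 0.52, while the list median of 0.14 became -0.11 with values as deposited, where the median of all genes was -0.27. Endothelial genes fell for 8 of 16 members (10 adjusted over the list alone), with Plvap at -0.74 ± 0.11 and Robo4, of the angiogenesis list, at -0.65 ± 0.11. Camera gave adjusted p = 6.89e-08, 0.00157 and 7.77e-05 for these 3 lists, and adjusted p = 0.470 for each with an estimated correlation. The T cell receptor genes Cd3d and Cd3g rose by 0.50 ± 0.09 and 0.41 ± 0.06, with values as deposited both did not pass, at 0.18 and 0.096, and Cd3d did not pass with arrays centred on their medians either. Nr1d2 did not pass with values as deposited, at 0.21, and C1qa lost its call in 3 of the 8 fits without 1 array. Erythroid genes had a median of -0.75 and cell cycle genes -0.44, with 0 of 18 and 0 of 30 members past the limma threshold over all genes or adjusted over the list alone (camera adjusted p = 0.000104 and 2.12e-06; adjusted p = 0.629 for both with an estimated correlation). Alb varied between 4.61 and 12.11 across the 8 spleen arrays.

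In spleen 1591 of 11356 genes passed, 799 higher and 792 lower, and of the 51 that changed at least 2-fold 41 fell. Swim and control arrays did not overlap for 23.7% of genes, against 2.86% by chance. The count was 5127 (66 higher, 5061 lower) with values as deposited, 1631 (281 higher, 1350 lower) with arrays centred on their medians, 597 with 1 fit of all 54 arrays, and 0 in limma with the signal range of the array as a covariate, against 1189 at an unadjusted p under 0.05. It was 571, 776, 702 and 854 without control replicates 25, 26, 27 and 28, and 735 and 955 without swim replicates 31 and 32.

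In brain, 56 of 11621 genes passed, 50 higher and 6 lower, and 27 of the rises and 0 of the falls in limma, among 1898 genes at an unadjusted p under 0.05, were of genes not annotated as protein-coding. Most genes tested were protein-coding, 11299 when fitted alone. Calls of genes not annotated as protein-coding also leaned to rises in kidney (52 rises and 11 falls) and spleen (42 and 5). They did not in liver (3 and 3) or muscle (24 and 26). The long noncoding RNA 9530091C08Rik rose by 1.90 ± 0.21 (n = 4 and 4, limma adjusted p = 0.0102), Phxr4 by 1.43 ± 0.18, 1700086D15Rik by 1.43 ± 0.13, 2310067E19Rik by 1.32 ± 0.19 and Mir598 by 1.08 ± 0.07, and these were the 5 that changed at least 2-fold. The 6 falls were Pcsk1n, which encodes the neuroendocrine peptide precursor proSAAS, at -0.69 ± 0.07, Cyba at -0.62 ± 0.10, Chac1 at -0.52 ± 0.07, Dusp28 at -0.42 ± 0.07, Zfp94 at -0.34 ± 0.05 and Tomm40l at -0.32 ± 0.05. Of the 8 fits without 1 array, Cyba and Tomm40l lost their calls in 8, Dusp28 and Zfp94 in 7, Chac1, Phxr4 and 2310067E19Rik in 6 and 9530091C08Rik in 4, and Cyba and Zfp94 did not pass with arrays centred on their medians. Of 17 clock genes 0 passed over all genes in limma and 4 rose adjusted over the list alone, with Per2 at 0.75 ± 0.14 and Per3 at 0.48 ± 0.08, while the list median of 0.17 became -0.05 with values as deposited, where the median of all genes was -0.20. Of 12 macrophage genes 0 passed over all genes in limma and 3 fell adjusted over the list alone, with Lyz2 at -0.71 ± 0.14 and C1qa at -0.44 ± 0.11, and the microglia list had a median of -0.25 with 0 of 12 past the limma threshold. The 3 lists had camera adjusted p = 0.00107, 0.000276 and 0.000784, and adjusted p = 0.916 for each with an estimated correlation. The cerebellar gene Gabra6 varied between 12.27 and 13.91 across the 8 brain arrays.

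The brain count was 3 with values as deposited (9530091C08Rik, Phxr4 and 1700086D15Rik), 61 (42 higher, 19 lower) with arrays centred on their medians, 129 with 1 fit of all 54 arrays, 3122 (1346 higher, 1776 lower) with array weights, 29 with a 60% filter, 20 (18 higher, 2 lower) with the signal range as a covariate and 4 among protein-coding genes alone (Pcsk1n, Apex2, Scube2 and Sox21, the last 3 named after their values were seen). It was 15, 18, 16 and 16 without control replicates 33, 34, 35 and 36, and 22 and 15 without swim replicates 38 and 39. Swim and control arrays did not overlap for 12.1% of genes, against 2.86% by chance.

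In muscle, the tissue that worked in swimming, Lcn2 rose by 2.41 ± 0.21 (n = 4 control and 3 swim, limma adjusted p = 0.00395). Genes of fatty acid and triglyceride synthesis rose for 8 of 23 members, with 0 falls in limma and 12 rises adjusted over the list alone (camera adjusted p = 6.74e-07; adjusted p = 0.880 with an estimated correlation). The elongase Elovl6 rose by 2.38 ± 0.62, fatty acid synthase Fasn by 2.22 ± 0.58, Acly by 1.81 and Acaca by 1.57 ± 0.38. Each of these 4 lost its call in 6 of the 7 fits without 1 array. Adipocyte genes had a median of 0.73 in muscle with 0 of 10 past the limma threshold (camera adjusted p = 0.00918; adjusted p = 0.880 with an estimated correlation), and Adipoq stood at 9.60 and 9.20 in swim replicates 46 and 47 and between 6.27 and 8.41 in the other 5 arrays. Clock genes rose for 9 and fell for 3 of 17 members (10 and 3 adjusted over the list alone), with Ciart at 2.22 ± 0.30, Per2 at 1.93 ± 0.19 and Arntl at -1.64 ± 0.15 (camera adjusted p = 0.00522; adjusted p = 0.880 with an estimated correlation).

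Collagen and matrix genes fell in muscle for 12 of 32 members (14 falls and 1 rise adjusted over the list alone), with Col3a1 at -0.97 ± 0.13, Col4a1 at -0.86 and Col5a3 at -0.79 ± 0.09. Macrophage genes fell for 3 of 16 members (7 adjusted over the list alone), with C1qb at -0.41 ± 0.08 and with Mpeg1 at a limma adjusted p = 0.0454. Endothelial genes rose for 4 of 16 members (9 rises and 1 fall adjusted over the list alone), with von Willebrand factor, Vwf, at 0.57 ± 0.09. Camera gave adjusted p = 0.000233, 0.00112 and 0.00112 for these 3 lists, and adjusted p = 0.880 for each with an estimated correlation. The pyruvate dehydrogenase kinase Pdk4 fell by 0.95 ± 0.20, the atrophy-linked ligase Trim63 by 0.61 ± 0.13 and Egr1 by 0.84 ± 0.18. Of 19 endurance exercise-response genes 3 fell and 0 rose in limma, also adjusted over the list alone, including Esrra at -0.35 ± 0.08 (camera adjusted p = 0.439). Of the 7 fits without 1 array, Esrra and Mpeg1 lost their calls in 6, Pdk4, Egr1 and C1qb in 5, Trim63 in 4 and Ciart and Vwf in 1, and 14 of the 31 genes of the rule followed in muscle passed without any 1 array. With values as deposited Esrra, C1qb and Vwf did not pass. The myelin gene Pmp22 rose by 1.17 ± 0.12 and the acute phase gene Orm3 by 1.06 ± 0.13.

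In muscle 1289 of 11347 genes passed, 645 higher and 644 lower, and 52 changed at least 2-fold. Swim and control arrays did not overlap for 28.6% of genes, against 5.71% by chance. The count was 393 (89 higher, 304 lower) with values as deposited, 890 (211 higher, 679 lower) with arrays centred on their medians, 599 with no filter, 625 with 1 fit of all 54 arrays, 578 (365 higher, 213 lower) with the signal range as a covariate and 2754 with array weights. It was 443, 847, 514 and 495 without control replicates 41, 42, 43 and 44, and 69 and 479 without swim replicates 46 and 47.

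**Figure D2:**
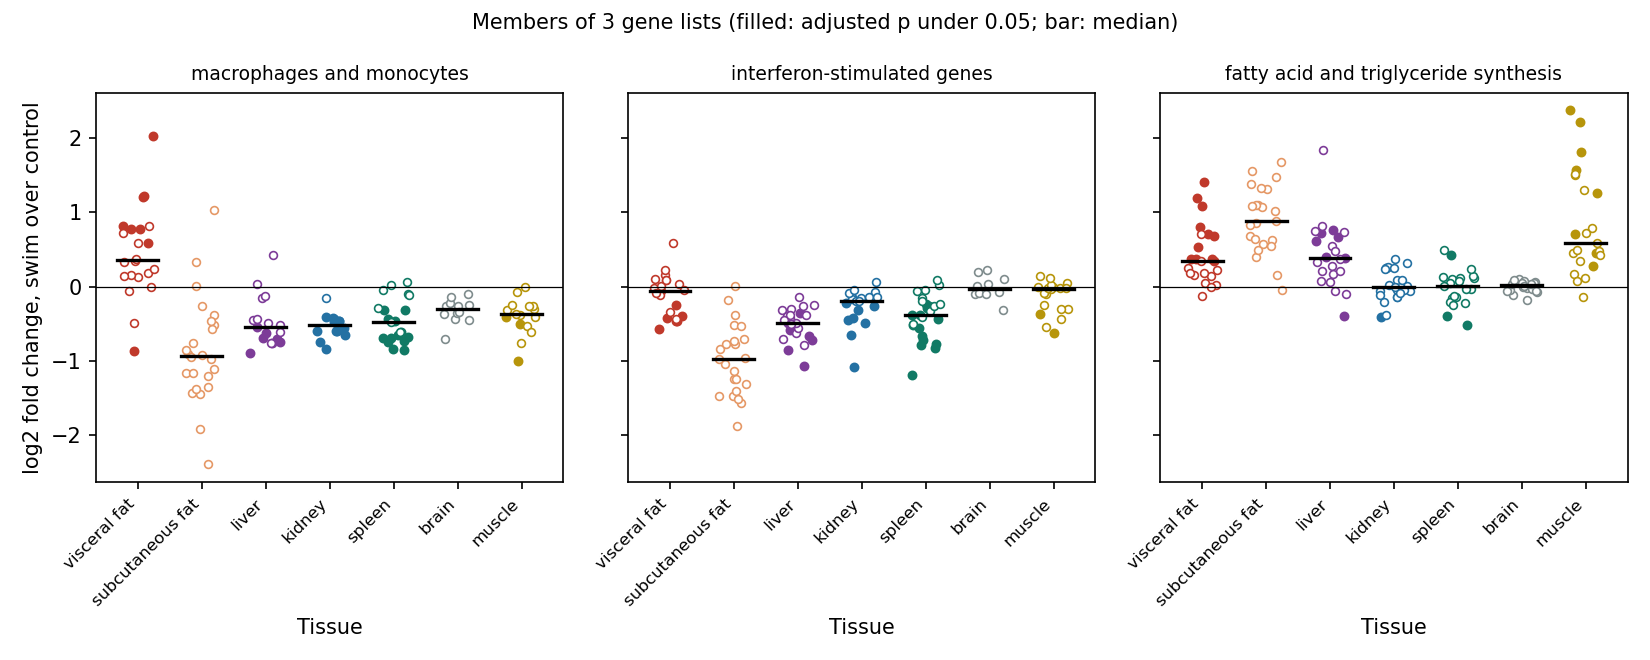
Log2 fold change of swim over control (vertical axis) for each measured member of 3 gene lists in the 7 tissues (horizontal axis). Filled points passed the adjusted threshold of 0.05 in limma and bars mark the medians, which for the macrophage list were 0.36 in visceral fat and below 0 in the other 6 tissues.

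The average effect over the 6 organs outside muscle asks whether a gene's mean change over them differed from 0, which 1 organ alone can bring about. Hamp2 passed with an average of 0.77 ± 0.06, with 4.37 in liver and between -0.39 and 0.36 in the other 5 organs. Arntl fell by 1.27 ± 0.07 on average (54 arrays, limma adjusted p = 7.91e-19) and was lower in 5 of the 6 organs, with spleen at 0.05. Ciart rose by 1.75 ± 0.10, Per3 by 1.46 ± 0.08, Per2 by 1.31 ± 0.08, Nr1d2 by 0.72 ± 0.05, and Wee1, a cell cycle kinase under clock control, by 0.75, and each of these 5 was higher in all 6 organs. Nfat5, a regulator of the response to osmotic stress, rose by 0.44 ± 0.03 and the Argonaute gene Ago3 by 0.37 ± 0.03, each higher in all 6 organs. In all 4097 of 14847 genes passed, 1948 higher and 2149 lower, and 1327 of them had the same sign in all 6 organs. The limma test takes the 54 arrays as independent, and its p may be too small if tissues share mice. With subcutaneous fat left out, a treatment added after the data were seen, 4906 passed, of which 3130 were shared with the 4097. With the 6 organs kept, the count was 1441 (394 higher, 1047 lower) with values as deposited. In simulated data 19.7% of the calls of this test were of unchanged genes. That share depends on how many genes were changed in the simulation and on noise drawn independently for each probe set. It therefore does not give the share among the real calls.

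Calls shared between tissues were counted per direction. By these counts 52 genes were called higher and 30 lower in at least 4 tissues, and 10 higher and 3 lower in at least 5. The 10 were Per2, Per3, Tef, Ankrd12, Nfat5, Utrn, Lncpint, Cplane1, 9530091C08Rik and Phxr4, and the 3 were Irf7, Dtx4 and Tomm40l, where those outside the naming rule were named after their values were seen. C1qb was called lower in liver, kidney, spleen and muscle. Adgre1 and Mpeg1 were called lower in the same 4 tissues and higher in visceral fat.

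**Figure D3:**
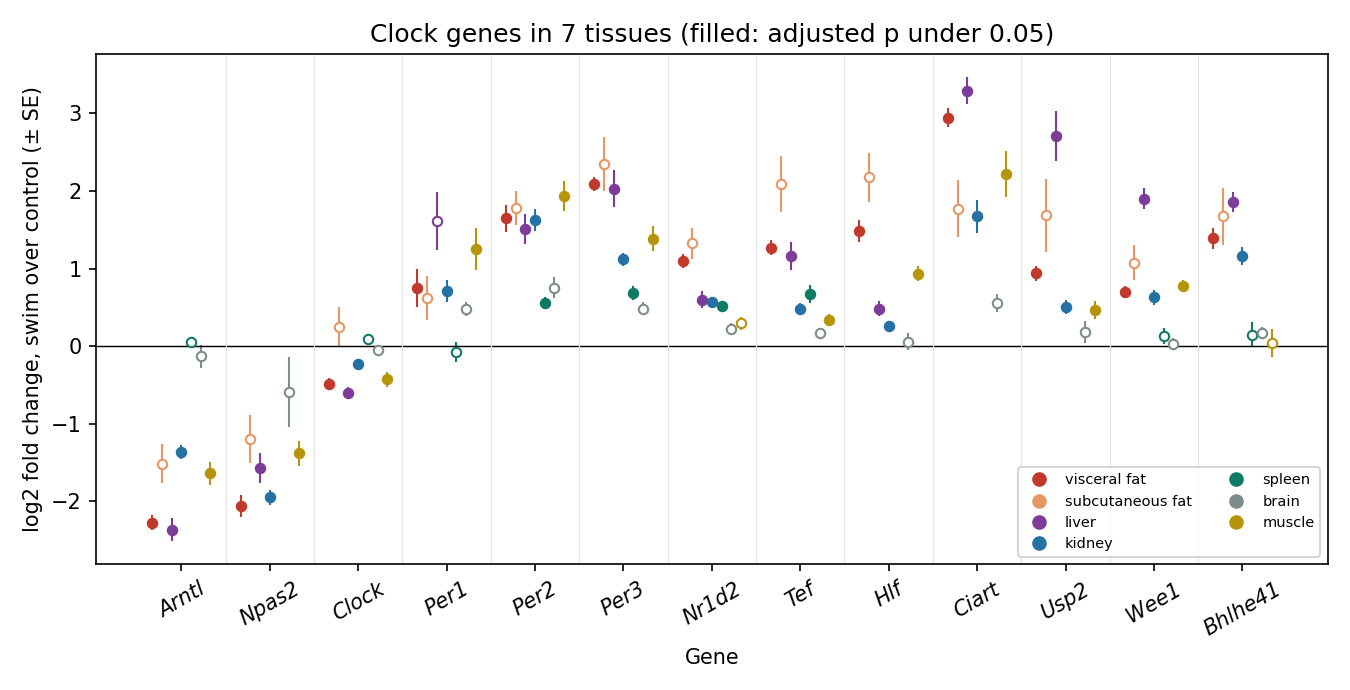
Log2 fold change of swim over control with its SE (vertical axis) for the 13 clock list genes called in at least 3 tissues (horizontal axis), 1 point per tissue where the gene was measured above the filter. Filled points passed the adjusted threshold of 0.05 in limma, and Ciart reached 3.29 in liver while Arntl stood at 0.05 in spleen.

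The F test asks which genes responded differently between tissues. Hamp2 rose by 4.37 in liver and lay between -0.39 and 0.36 in the other 6 tissues (limma adjusted p of the F test = 3.26e-21). Ltf fell by 2.53 in spleen and lay between -0.17 and 0.21 elsewhere. Rgs16 was at 3.15 in liver and -0.70 in subcutaneous fat. The phosphate transporter gene Slc34a2 stood at -2.29 in liver, with -0.83 in kidney and 0.32 in subcutaneous fat. Arntl ranged from -2.37 in liver to 0.05 in spleen. Lcn2, singled out after its values were seen, stood at 2.41 in muscle, -3.23 in spleen and -2.20 in liver (limma adjusted p of the F test = 1.72e-05). In all 5322 of 14847 genes passed, and with each tissue's own spread, added after the data were seen, 5386 passed, of which 3650 were shared with the 5322. In simulated data with 400 changed genes, 53.3% of the calls of the first version and 14.0% of the calls of the second were of unchanged genes. These shares depend on how many genes change and on noise drawn independently for each probe set. They therefore do not give the share among the real calls. Both lie above the threshold of 0.05, so the counts are likely to overstate the number of genes that differ. The count was 1239 with values as deposited and 8993 without subcutaneous fat control replicate 17. With all arrays of subcutaneous fat left out, a treatment added after the data were seen, 5216 passed, of which 3497 were shared with the 5322.

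The fat depots were compared to ask whether visceral and subcutaneous fat responded differently. In limma 0 of 12122 genes passed, with 2431 at an unadjusted p under 0.05. The smallest p were those of Tcirg1, a proton pump subunit gene, with 0.66 in visceral and -0.58 in subcutaneous fat, and the myeloid receptor gene Cd300c2, with 1.09 and -1.10, both at adjusted p = 0.0927. Itgax stood at 0.82 in visceral and -1.36 in subcutaneous fat (adjusted p = 0.155). Without subcutaneous fat control replicate 17, 4818 genes passed, and without swim replicate 23 of that tissue 1 passed, Tlcd4 at -3.27.

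Pairs of tissues were compared to ask how alike their responses were across genes. In permutation tests 10 of 21 pairs passed at an adjusted threshold of 0.05, against 6 with no filter and 5 with Spearman's correlation. Visceral fat and kidney had the highest correlation, at 0.393 across 10514 genes (permutation p = 0.0099, the smallest that 100 draws allow, adjusted p = 0.0297). Of genes called in both, 410 were higher in both against 127 expected, 432 lower in both against 169 expected, and 74 opposite. Subcutaneous fat and spleen had a correlation of -0.020 (permutation p = 0.812). The labels were drawn apart in each tissue, and whether tissues share mice is not given. If they do, differences between the mice themselves could raise the correlations and the shared calls, which these tests do not cover.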

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

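The tests of explanations and of other splits of the arrays in this part were chosen only after the data were seen, and the F test between tissues was set before.

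Clock genes were shifted in several tissues, with 58 called pairs of gene and tissue. Scaling of the arrays as the cause is argued against by the contrast, in deposited log2 signal, of the clock genes that rise with Per2 minus Arntl, Npas2 and Clock, from which a factor of the whole array cancels. It differed between the groups by over 2 SE in 5 of the 5 tissues with called clock genes, from 0.38 ± 0.06 in spleen to 3.81 ± 0.51 in liver. The signal range of the arrays as the whole cause is argued against outside spleen, where with that range as a covariate 54 of 54 pairs had at least 0.5 of their log2 change and 46 stayed past the threshold. In spleen it stays open. There 0 of the 4 called clock genes by limma, each at an unadjusted p under 0.05, stayed past it. Their log2 changes were 0.52 to 0.69 with SE of 0.065 to 0.118 before and 0.50 to 0.70 with SE of 0.139 to 0.250 after, so the calls ended because the SE grew. A different time of day at tissue collection in the swim groups stays open, since 0 of 53 called pairs moved against the order of 1 phase shift, and a shift caused by the swimming itself predicts the same order. The labels give the hours of the sessions but not of collection, so these 2 explanations cannot be told apart.

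Subcutaneous fat arrays differed from one another within a group. Lymph node tissue in some arrays may account for part of this. The B cell list mean as a covariate lowered the median residual SD to 0.751 of its value, against a median of 1 for permuted covariates. Without the covariate that SD was 0.330, against at most 0.138 in the other tissues, so spread remained. The adipocyte list mean was lowest in control replicates 18, 19 and 20, at 9.97 to 10.78, so the covariate does not single out lymph node tissue. Kidney RNA in swim replicate 22 is a candidate explanation for that array. There 96.8% of 124 kidney-specific probe sets were higher by over 1 log2 unit than in each other subcutaneous fat array. The same count was 0% for each of the other 7 arrays. It could hardly be otherwise, since swim replicate 22 was among the arrays they were compared with. The median of the 124 probe sets was 10.29 in swim replicate 22, 5.06 in the others and 11.38 in kidney controls. Swim replicate 23 was high in the muscle gene Ckm, at 11.52 against 5.53 to 7.55 in the other 7, and muscle tissue in that array was not tested and stays open. No biological explanation was tested, and swimming itself stays open as one for differences between the groups.

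The macrophage list was shifted lower in liver, kidney and muscle, with medians of -0.54, -0.52 and -0.37, by camera with the preset correlation but not with an estimated one (adjusted p = 0.260, 0.146 and 0.880). Of its members 7 of 17, 13 of 14 and 3 of 16 were called lower. Less blood in the organs of swim mice is argued against only as far as the erythroid list stands for blood. The macrophage median lay below the 25th percentile of that list in 3 of 3 organs. The medians of the erythroid list were 0.02, -0.03 and -0.08. A lower share of all non-parenchymal cells is argued against in the same way, in 3 of 3 organs, only as far as the endothelial list stands for them. The medians of that list were 0.08, 0.005 and 0.31. Other non-parenchymal cells were not tested, and the collagen and matrix list had a median of -0.28 in muscle, against 0.06 in liver. Scaling of the arrays is argued against in 2 of 2 organs, liver and kidney, where the list median less the median of all genes in deposited log2 signal, from which a factor of the whole array cancels, differed between the groups by -0.61 ± 0.18 and -0.53 ± 0.04. In muscle the shift relative to all genes was -0.35 with quantile normalization and -0.30 with values as deposited, where the list macrophages and monocytes in muscle stayed called by camera with the preset correlation (adjusted p = 1.21e-05, against 4.92e-07 to 0.00925 without 1 array, 0.169 by fry, a test against no change rather than against other genes, and 0.880 with an estimated correlation). This counts against scaling there, but between arrays the difference was -0.35 ± 0.24, or 1.46 SE, within its spread, so scaling is not excluded in muscle. In spleen, where 13 of 21 members were called lower and the macrophage median was -0.47, the 25th percentiles of the erythroid and endothelial lists were -0.89 and -0.56, so neither less blood nor a lower share of non-parenchymal cells is argued against in that organ. What stays open, as a hypothesis found on these same data, is that swimming may lower the number of macrophages in liver and kidney or the expression of these genes in them, which the arrays do not separate. In kidney the brown fat gene Ucp1 was lower as well, at -1.31 ± 0.52 (limma adjusted p = 0.0959), and the adipocyte list had a median of -0.18 (camera adjusted p = 0.464), so less adherent fat in the swim kidneys stays open. The signal range of the arrays was not tested for this list.

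Other splits of the arrays into groups of the same sizes were fitted. In 5 of the tissues with calls and in brain, 1 of 35 splits gave as many calls, the real one. That share is the smallest that 35 splits allow, so it argues against chance in each tissue but does not exclude it. In brain the highest other split gave 1492 genes at an unadjusted p under 0.05 in limma, against 1898 for the real one. The real counts and the highest of the other splits were 2677 and 0 in visceral fat, 448 and 2 in liver, 2836 and 2 in kidney, 1591 and 1 in spleen, 56 and 3 in brain, and 1289 and 1 in muscle. With 0 calls by limma in subcutaneous fat and for the difference between the fat depots, the splits were compared there by genes at an unadjusted p under 0.05. In subcutaneous fat 3 of 35 splits gave as many as the real 2489 and the highest other gave 5086, so chance cannot be excluded. Another split of those arrays gave 2638 calls, which points to a structure of the samples. For the depots 6 of 100 splits gave as many as the real 2431 and the highest other gave 5339, so chance cannot be excluded. Another split gave 3728 calls, which again points to a structure of the samples. For the average over 6 organs 1 of 100 splits gave as many, with 4097 against 2080, which argues against chance if the arrays are independent. The labels were shuffled apart in each tissue. Whether tissues share mice is not given, and if they do, these splits cannot exclude chance. For the effect that differs between tissues 2 of 100 splits gave as many, with 5322 against 6066. That share is under 0.05, with the same limit, while the higher split points to a structure of the samples.

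The response differed between tissues for 5322 genes by the F test. The 10 of smallest adjusted p were Hamp2 (3.26e-21), Ltf (1.65e-14), Arntl and Rgs16 (1.51e-11 each), Slc34a2 (1.96e-09), Capn8 and Polr2e (8.27e-09 each), and Eif2b2, S100a8 and Wee1 (1.55e-08 each). With each tissue's own spread their adjusted p ranged from 5.19e-18 for Hamp2 to 0.00156 for S100a8. Polr2e stood at -0.60 in kidney and 0.39 in muscle, and Eif2b2 at -0.76 in kidney and 0.11 in brain.

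Single arrays lay far from the others of their group in 29 of 398 groups of values tested, 7.29%, where chance flags about 1 in 20 groups, or 19.9 here. The measure is the gap to the nearest other array over the whole range of the group. In visceral fat controls it was 0.837 for Ciart and 0.836 for 9530091C08Rik in replicate 1, 0.897 for Dgat1 in replicate 3, 0.864 for Egr1 in replicate 4 and 0.847 for Egfl7 in replicate 2. In visceral fat swim arrays it was 0.9 for Tef, 0.833 for Atp6v0d2, 0.928 for Mpeg1 and 0.978 for Fosl2 in replicate 5, and 0.945 for Kdr and 0.963 for Cdh5 in replicate 8. In subcutaneous fat it was 0.843 for Elovl6 in control replicate 19, and 0.905 for Itgax and 0.981 for C1qa in swim replicate 23. In liver swim arrays it was 0.852 for Wee1 and 0.934 for C1qb in replicate 56, and 1 for Cyp2c29 in replicate 53, where the other 3 swim arrays were tied at 15.52. In kidney it was 0.884 for Ifi30 in control replicate 11, 0.875 for Rtp4 in control replicate 9, 0.837 for Dusp1 in control replicate 10 and 0.853 for Cd68 in swim replicate 16. In spleen it was 0.832 for Slc15a2, 0.839 for Gp9 and 0.872 for Fmo2 in control replicates 27, 26 and 28, and 0.831 for Csf3r in swim replicate 32. In brain it was 0.871 for Mir598 in control replicate 33 and 0.95 for Phxr4 in swim replicate 40. In muscle it was 0.969 for Esrra and 0.92 for the median signal in control replicate 42, whose median signal was 45.9 against 63.1 to 64.6 in the other controls.

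Probe sets without a single gene symbol, which the gene tests left out, passed the same limma test for 399 of 2460 in visceral fat, 326 of 2423 in kidney, 138 of 2581 in spleen, 137 of 2331 in brain, 50 of 2568 in muscle and 5 of 2723 in liver. The share in brain, 5.88%, was above the 0.482% of genes called there. In the other tissues with calls it was below that of genes, as in visceral fat, with 16.2% against 23.4%, and muscle, with 1.95% against 11.4%. In brain 118 of the 137 were higher.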

How the results depend on the processing

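The fits with protein-coding genes alone, the signal range or the B cell list as a covariate, genes brighter in another tissue left out and the other treatments of spread across tissues were chosen only after the data were seen, and the others before. With values as deposited the counts were 601 in visceral fat, 4 in subcutaneous fat, 42 in kidney, 5127 in spleen, 3 in brain, 393 in muscle, 1239 for the difference between tissues and 1441 for the average, and with arrays centred on their medians 5209 in visceral fat. The median of all genes moved with scaling, to -0.22, 0.11 and -0.11 in visceral fat, subcutaneous fat and muscle with arrays centred on their medians. With values as deposited it moved to -0.10, 0.11, 0.11, -0.27, -0.20 and -0.23 in visceral fat, subcutaneous fat, kidney, spleen, brain and muscle, so changes are to be read relative to it. With 1 fit of all 54 arrays the counts were 6626 in subcutaneous fat, 382 in kidney, 597 in spleen, 129 in brain and 625 in muscle, and with array weights 5715 in subcutaneous fat, 3122 in brain and 2754 in muscle. With no filter they were 294 in liver and 599 in muscle, with the 60% filter 29 in brain, and with the trend and robust options 707 in liver. With the signal range as a covariate they were 1 in subcutaneous fat (9530091C08Rik), 181 in liver, 20 in brain, 578 in muscle and 0 in spleen, where limma still had 1189 genes at an unadjusted p under 0.05. Among protein-coding genes alone brain had 4, and with the B cell covariate and swim replicate 22 left out subcutaneous fat had 1. Of 93 list shifts 0 held with an estimated correlation in limma's camera and 36 held with fry, which called 41 lists in all. Of the 21 pairs 6 passed with no filter and 5 with Spearman's correlation, against 10. The cause was not tested for any of these, apart from the fewer genes tested under the filters and among protein-coding genes.

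Without 1 array each, the counts ranged from 1695 to 2340 in visceral fat, 0 to 3976 in subcutaneous fat, 127 to 529 in liver, 2119 to 2467 in kidney, 571 to 2181 in spleen, 15 to 69 in brain, 69 to 1127 in muscle, 3833 to 8993 for the difference between tissues, 3834 to 5942 for the average and 0 to 4818 for the fat depots, and called lists from 89 to 97. The upper ends for subcutaneous fat, the difference between tissues, the average and the depots came without subcutaneous fat control replicate 17, at 3976, 8993, 5942 and 4818. The list skeletal muscle fibres in liver reversed without liver control replicate 52, at adjusted p = 0.0567, and over the fits without 1 array its adjusted p ranged from 0.00011 to 0.0579. By limma and camera no other result reversed among the 224 named gene and tissue pairs and 93 lists in the alternatives run. The medians of 5 called lists changed sign with scaling, those of fatty acid and triglyceride synthesis and endothelial cells in visceral fat to -0.08 and -0.06 with arrays centred on their medians, and with values as deposited those of the clock in spleen and brain to -0.11 and -0.05 and of the unfolded protein response in spleen to -0.18. Of the 224 pairs 155 kept their side of the threshold with 1 fit of all 54 arrays (53 lost and 16 gained a call), 160 with the signal range as a covariate (64 lost), 167 with values as deposited and 209 with arrays centred on their medians, and of 1704 fits of these pairs without 1 array 1440 did. All other settings left the counts within 1.5 times. Low signal over background limits what dim genes can show, and the lowest 40% of probe sets were not tested.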

Other observations

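The genes in this part other than Xist and the organ markers were chosen after their values were seen. Sex markers were uniform, with Xist between 4.49 and 5.37 and the Y-linked gene Eif2s3y between 8.80 and 9.82 on the log2 scale across the 54 arrays. Ucp1, the uncoupling protein gene of brown fat, varied between 4.70 and 10.85 across the 8 subcutaneous fat arrays and between 4.61 and 8.21 across the 7 muscle arrays. In muscle Alb, a liver gene, varied between 6.02 and 11.30. The Y-linked multicopy genes Sly and Gm20806 rose in spleen by 2.18 ± 0.62 and 1.64 ± 0.46, and the peptide transporter gene Slc15a2 rose by 2.21 ± 0.50. Sly, Gm20806 and Slc15a2 lost their calls in 6, 6 and 5 of the 8 fits without 1 array.

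In liver the hypoxia list had 2 rises and 1 fall among 18 members and did not pass (camera adjusted p = 0.0859), with the mitophagy gene Bnip3 up by 0.72 ± 0.10 and Pdk1 by 1.03 ± 0.16, though Pdk1 lost its call in 4 of the 7 fits without 1 array. In kidney 5 of 17 genes of the amino acid response fell and 1 rose (camera adjusted p = 0.159), with Psat1 at -0.67 and Asns at -0.46, enzymes of serine and asparagine synthesis, neither of which passed with values as deposited. In muscle the antioxidant list had 3 rises and 2 falls among 17 members (camera adjusted p = 0.522), with the detoxification genes Ephx1 up by 0.74 ± 0.08 and Gstm2 by 0.71 ± 0.10, neither of which passed with values as deposited, and Gstm2 lost its call in 1 of the 7 fits without 1 array. The ratio of the median to the 5th percentile of signal averaged 11.6 in visceral fat controls and 8.66 in swim arrays (n = 4 and 4, exact permutation p = 0.0286, adjusted 0.1 over 7 tissues), and 10.0 and 7.40 in spleen (exact permutation p = 0.0286, adjusted 0.1). In brain the ratio averaged 12.1 and 9.82 (exact permutation p = 0.0571, adjusted 0.133). It was also lower in the swim arrays of liver and muscle, and higher in those of kidney (8.93 and 9.95) and subcutaneous fat (8.70 and 10.4).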
